A study of Rattus norvegicus with 18 samples.

How the data were processed

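Hearts of 18 male Wistar rat offspring aged 3 weeks were profiled by bulk RNA sequencing. Per the labels, their dams had received vehicle (7 offspring) or cannabidiol, a non-intoxicating cannabinoid of the cannabis plant, during gestation at 3 mg/kg/day (CBD3, 6 offspring) or 30 mg/kg/day (CBD30, 5 offspring). Per the labels' protocols, total RNA was extracted with a phenol reagent from frozen hearts and libraries were made with a stranded kit after enrichment of messenger RNA. The authors deposited whole-number counts per Ensembl gene, 1 column per sample. The submitters' processing notes name featureCounts, edgeR and the genome build mRatBN7.2. The aligner, the annotation release and the counting settings are not given in the sources used here, nor is any sharing of litters. P-values treat the offspring as independent, although the dams were dosed, and would be too small if littermates resemble each other.

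Each column carries a code of a pair of numbers, such as 3.1, that no label explains. The codes ending in digit 1 cover 4 vehicle, 3 CBD3 and 2 CBD30 samples, and those ending in digit 2 cover 3 of each group. The replicate number could be assigned to 14 columns. The other 4, all vehicle samples with codes ending in digit 1, were used as vehicle samples without a replicate number, because the labels of vehicle replicates 1 to 4 hold a pair of codes each. These samples are named here by their code.

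Scaled for library size, the deposited counts differed little between the last digits of the code. The library totals themselves did differ. The median absolute log2 difference between the digits was 0.0137 over the tested genes, the lowest of 100 divisions drawn within groups (lowest other 0.0604). Among 2555 genes with a mean count of 2 to 10, values of 2 were rarer than the mean of the values 1 and 3 by a ratio of 0.56. The table was analysed as counts. Whether the counts were adjusted for this digit before deposit is not given in the sources used here, and p-values do not account for such a step.

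The table holds 30560 genes, and 17009 passed filterByExpr by group (minimum count 10, minimum total count 15). Counts were scaled by TMM, and groups were compared in 1 fit of all 18 samples with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3. P-values were adjusted by the Benjamini-Hochberg method over the tested genes, with a threshold of 0.05. Standard errors of log2 fold changes were derived from the F statistic, and intervals are at the 95% level. CPM values are TMM-scaled, and log2 CPM used a prior count of 2. Comparisons of library measures used exact two-sided permutation tests. No pair of libraries within a group agreed within sampling noise (46 pairs, lowest chi-square per degree of freedom 34.4), so no pair was merged as 1 library deposited again. That each library comes from a separate animal rests on the labels.

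The pipeline was tested on simulated counts of 17009 genes, 200 of them changed, drawn from genes with an average above 1 CPM. Genes were simulated independently, without the shared variation of the real samples. The shares recovered are therefore not the power of the real comparisons. For CBD3 against vehicle it recovered 53.7% of 67 genes changed 1.5-fold and 92.5% of 67 changed 2-fold. For CBD30 against vehicle the shares were 56.7% and 82.1%, and for CBD30 against CBD3 37.3% and 88.1%.

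The comparisons, tests, gene lists and most alternatives were fixed before the data were examined. The table names genes by Ensembl ID only. The reference table used for symbols (assembly GRCr8, 47357 genes) holds an Ensembl ID for 0 of its genes, so 0 of 30560 IDs were paired with a symbol. The 38 gene lists fixed in advance were therefore not tested. The rule for named genes required genes past the threshold with a symbol, and it could not be applied. In its place 4 IDs are given, by a rule made after the calls were seen. They are the 2 IDs per direction with the smallest unadjusted p for CBD30 against vehicle, among IDs with a mean of at least 1 CPM whose difference in mean log2 CPM kept its sign when each sample was left out.

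Alternatives covered relative log expression factors, library size only, other low-count filters, only the groups compared, the last digit of the code as a covariate, a replicate block, each sample left out, DESeq2 1.42.0 on all genes and on the genes tested with edgeR, and limma 3.58.1 with voom, with sample quality weights, or with the first number of the code as a shared unit. Each comparison was set beside 100 divisions of the same samples, the real one included.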

Results

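Bulk RNA sequencing measured gene expression in the hearts of 3-week-old male rat offspring after gestational exposure to vehicle (n = 7), cannabidiol at 3 mg/kg/day (CBD3, n = 6) or cannabidiol at 30 mg/kg/day (CBD30, n = 5). The libraries held 44321480 to 80451013 counts in the vehicle group, 56992503 to 89240727 in CBD3 and 44127009 to 82220752 in CBD30. Between 19615 and 20474 genes had at least 1 count in a library. The 10 most abundant genes took 28.0% ± 3.04 of the counts in vehicle hearts (SD, n = 7), 27.4% ± 1.82 in CBD3 hearts (n = 6) and 27.9% ± 1.42 in CBD30 hearts (n = 5). These shares did not separate the groups (exact two-sided permutation p = 0.699 for CBD3 against vehicle and 0.965 for CBD30 against vehicle, Benjamini-Hochberg adjusted p = 0.92 and 0.965 over 12 tests of library measures). The samples whose code ends in digit 1 held more counts than those ending in digit 2, with a mean of 77101278 counts (SD 8718920, n = 9) against 55489942 counts (SD 9376002, n = 9; exact two-sided permutation p = 0.000206).

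The first principal component of log2 CPM held 29.8% of the variance. Its mean score was -16.4 ± 36.1 in vehicle (SD, n = 7), 6.99 ± 15.7 in CBD3 (n = 6) and 14.6 ± 31.0 in CBD30 hearts (n = 5). No pair of groups was separated on it (exact two-sided permutation p = 0.175 for CBD3 against vehicle, 0.158 for CBD30 against vehicle and 0.662 for CBD30 against CBD3; adjusted p = 0.61, 0.61 and 0.92 over the 12 tests). The samples farthest from the centre were the vehicle samples coded 2.1 (-65.0) and 1.1 (-57.9) and the CBD30 sample coded 2.1 (65.5).

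**Figure D1:**
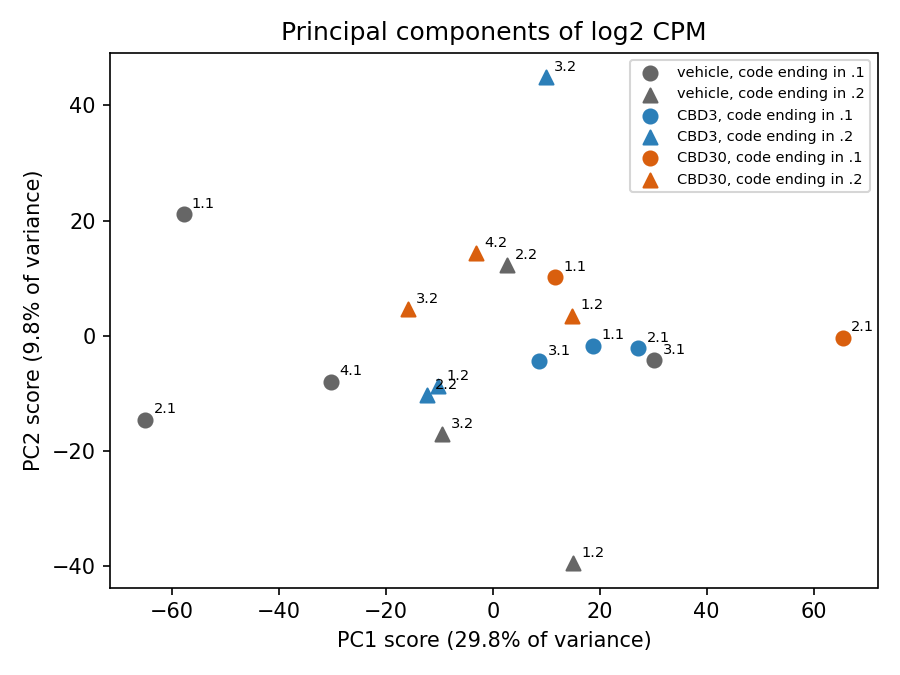
Scores of the 18 heart samples on the first (x axis) and second (y axis) principal components of log2 CPM, coloured by group, with the shape giving the last digit of the sample code. Vehicle samples span -65.0 to 30.2 on the first component and overlap both cannabidiol groups.

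The comparison of CBD30 with vehicle addresses whether the higher gestational dose was followed by altered cardiac expression in male offspring. ENSRNOG00000000860 had the smallest p-value, with 53.5 ± 8.68 CPM in CBD30 (SD, n = 5) against 86.6 ± 9.27 CPM in vehicle hearts (n = 7), a log2 fold change of -0.69 ± 0.11 (SE; edgeR adjusted p = 0.0751). ENSRNOG00000013841 had 11.6 ± 2.09 CPM in CBD30 against 22.9 ± 3.77 CPM in vehicle hearts, a log2 fold change of -0.98 ± 0.18 (SE; edgeR adjusted p = 0.121). In the other direction, ENSRNOG00000039571 had 6.34 ± 1.70 CPM against 3.28 ± 0.225 CPM, a log2 fold change of 0.95 ± 0.16 (SE; edgeR adjusted p = 0.0751), and ENSRNOG00000018214 had 22.9 ± 2.15 CPM against 15.4 ± 1.81 CPM, a log2 fold change of 0.57 ± 0.11 (SE; edgeR adjusted p = 0.121). For each of these 4 IDs, which were picked by p-value, all 5 CBD30 samples lay outside the range of the 7 vehicle samples. DESeq2 called all 4 (adjusted p = 0.00025 for ENSRNOG00000000860, 0.000812 for ENSRNOG00000013841, 0.000225 for ENSRNOG00000039571 and 0.00162 for ENSRNOG00000018214). The limma voom fit called none of them (adjusted p = 0.107 to 0.152). The sources used here do not pair these IDs with gene symbols, and what the genes do is not given.

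**Figure D2:**
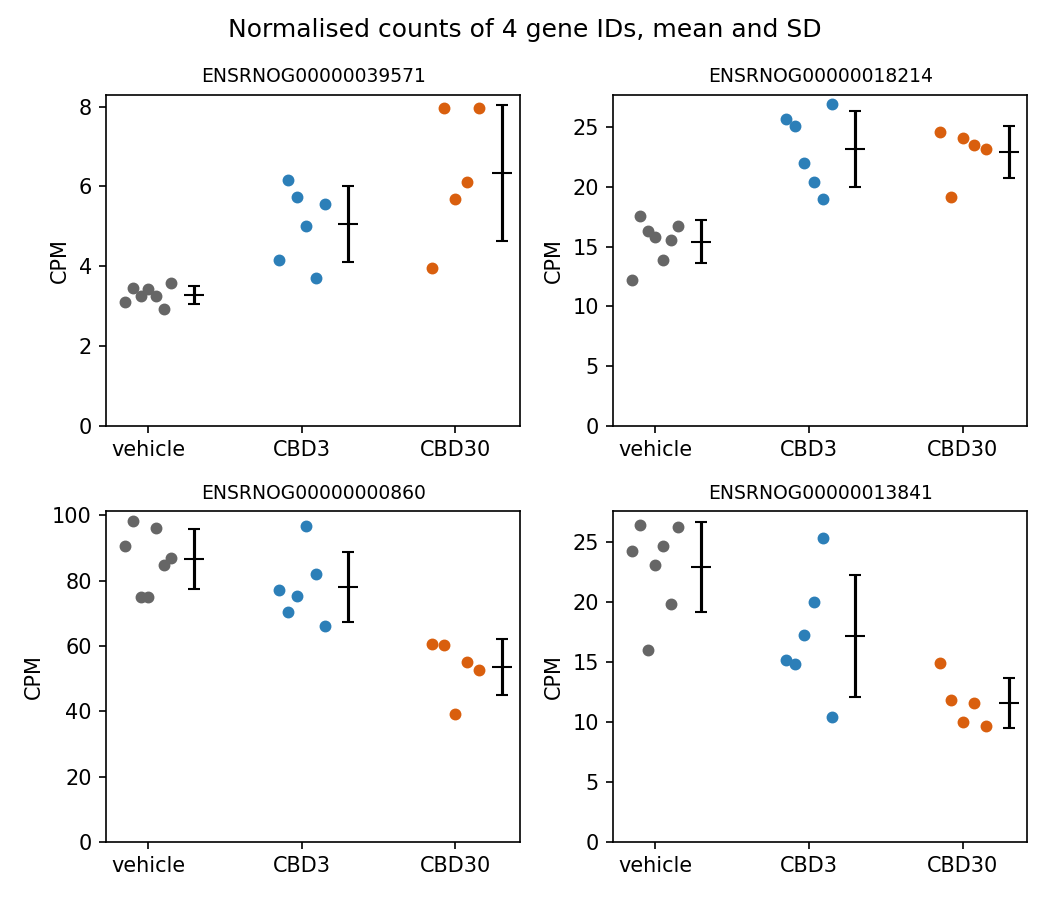
TMM-scaled CPM (y axis, from 0) of 4 gene IDs in each vehicle, CBD3 and CBD30 heart, with 1 point per sample and the mean and SD beside each group. All 5 CBD30 points lie above the vehicle range for ENSRNOG00000039571 and ENSRNOG00000018214 and below it for ENSRNOG00000000860 and ENSRNOG00000013841.

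Across the transcriptome, 0 of 17009 genes passed an adjusted p of 0.05 for CBD30 against vehicle with edgeR, and 2 genes had an adjusted p under 0.1. At an unadjusted p under 0.05 there were 2794 genes (16.4%, where 850 is the nominal 5%), 1550 higher and 1244 lower in CBD30. The 95% interval of the fold change lay within 2-fold either way for 92.6% of the 13527 genes with a mean of at least 1 CPM. The call differed between fits: DESeq2, with its own size factors and 24347 genes tested, called 134 genes (42 higher, 92 lower), and 160 (54 higher, 106 lower) when given the 17009 genes. The limma voom fit called 0, and edgeR called 267 (148 higher, 119 lower) without the vehicle sample coded 3.1. With edgeR 1 gene was called without CBD30 replicate 1, and the unadjusted count was 1606 without CBD30 replicate 2.

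By the labels, the last digit of the code divides the samples into sets that share no animal, so the CBD30 difference could be measured in each. Whether the sets share dams is not given. Across genes, which are not independent replicates, the log2 fold changes in the samples ending in digit 1 (2 CBD30, 4 vehicle) and in those ending in digit 2 (3 CBD30, 3 vehicle) had a Pearson correlation of -0.0495. Of 100 regroupings within the digits, the real one included, 61 gave a correlation as high. At an unadjusted p under 0.05 there were 4265 genes in the digit 1 samples and 798 in the digit 2 samples. The 3 samples farthest out on the first component, vehicle 1.1 and 2.1 and CBD30 2.1, are all in the digit 1 set. Without them the count over both digits was 1133, so the digit and those samples were not separated. The 4 IDs had the same sign in both sets, with ENSRNOG00000039571 at 0.85 ± 0.24 and 1.02 ± 0.24 (log2 fold change, SE) and ENSRNOG00000000860 at -0.49 ± 0.17 and -0.86 ± 0.15. These IDs were chosen on all of the samples, so that agreement in sign is not independent evidence.

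**Figure D3:**
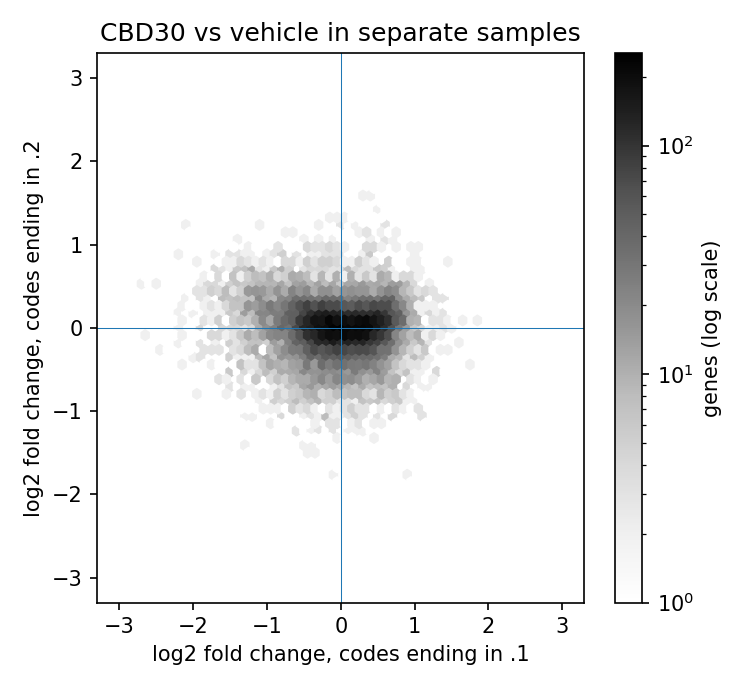
Difference in mean log2 CPM between CBD30 and vehicle hearts for each tested gene, in samples with codes ending in digit 1 (x axis) and in digit 2 (y axis), shaded by the number of genes on a log scale; 23 of 17009 genes lie beyond the axes at 3. The cloud shows no slope (Pearson correlation -0.0495) and is wider along the x axis.

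The comparison of CBD3 with vehicle asks the same of the lower dose. ENSRNOG00000018214 had the smallest p-value, with 23.2 ± 3.2 CPM in CBD3 (SD, n = 6) against 15.4 ± 1.81 CPM in vehicle hearts (n = 7), a log2 fold change of 0.59 ± 0.10 (SE; edgeR adjusted p = 0.211, DESeq2 0.000677). ENSRNOG00000039571 had 5.05 ± 0.954 CPM in CBD3 hearts, a log2 fold change of 0.62 ± 0.15 (SE; edgeR adjusted p = 0.504). All 6 CBD3 samples lay above the highest vehicle sample for both IDs. Both were picked by the CBD30 comparison with the same 7 vehicle samples, so that separation is not independent evidence. ENSRNOG00000000860 and ENSRNOG00000013841 had 78.0 ± 10.7 and 17.1 ± 5.10 CPM, log2 fold changes of -0.15 ± 0.11 and -0.42 ± 0.17 (SE), with CBD3 and vehicle samples overlapping.

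With edgeR 0 of 17009 genes passed an adjusted p of 0.05 for CBD3 against vehicle, and 1518 (8.9%) had an unadjusted p under 0.05, 662 higher and 856 lower in CBD3. DESeq2 called 19 genes (9 higher, 10 lower), or 8 (5 higher, 3 lower) when given the 17009 genes, and limma voom 0. For 94.3% of the 13527 genes with a mean of at least 1 CPM the 95% interval lay within 2-fold either way. The unadjusted count moved with single libraries, to 962, 929 and 2823 without the vehicle samples coded 1.1, 2.1 and 3.1 and to 992 without CBD3 replicate 6. Log2 fold changes in the digit 1 and digit 2 samples had a Pearson correlation of -0.134 across genes, and 86 of 100 regroupings gave one as high.

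Between the doses, ENSRNOG00000000860 was at 53.5 ± 8.68 CPM in CBD30 (SD, n = 5) and 78.0 ± 10.7 CPM in CBD3 hearts (n = 6), a log2 fold change of -0.54 ± 0.12 (SE; edgeR adjusted p = 0.999), with all 5 CBD30 samples below the lowest CBD3 sample. It was -0.30 ± 0.17 in the digit 1 and -0.74 ± 0.15 in the digit 2 samples (log2 fold change, SE). ENSRNOG00000018214 differed by -0.017 ± 0.11 (log2, SE), with a 95% interval of -0.25 to 0.21, and the sign of so small a difference changed in several alternative fits. With edgeR 0 of 17009 genes passed an adjusted p of 0.05 for CBD30 against CBD3, and 294 (1.7%) had an unadjusted p under 0.05, fewer than the nominal 850. DESeq2 called 1 gene and limma voom 0. For 96.7% of the 13527 genes with a mean of at least 1 CPM the 95% interval lay within 2-fold either way.

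**Figure D4:**
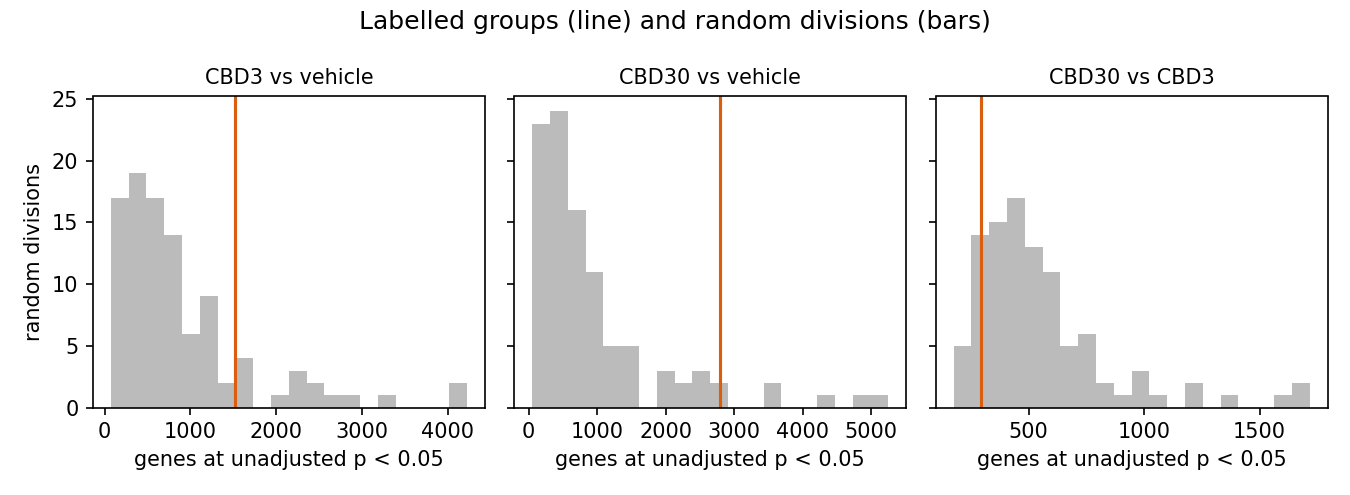
Number of genes at an unadjusted p under 0.05 (x axis) in each comparison, for the labelled groups (line) and for the other divisions among 100 of the same samples (bars, number of divisions on the y axis). The labelled groups gave 1518, 2794 and 294 genes, and the highest other divisions 4224, 5248 and 1717.

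The log2 fold changes of both doses against vehicle were compared across the 17009 genes. Their Pearson correlation was 0.761 and their Spearman correlation 0.785, and 82.5% of genes had the same sign. Both comparisons use the same 7 vehicle samples. Counts simulated for all 18 samples with no effect gave a Pearson correlation of 0.443 and the same sign for 64.6% of genes. Genes were drawn independently there, without the shared variation of the real samples. The other regroupings of the real samples, among 100, gave correlations of -0.29 to 0.758 (median 0.398), so the simulated value is not a full baseline. The covariance was 0.0649 against 0.0257 in the simulation. With the vehicle samples split into 3 and 4, so that the doses shared no control, the Pearson correlation averaged 0.315 over 70 assignments (-0.11 to 0.49) and the covariance 0.0345, with fewer vehicle samples behind each dose. Genes at an unadjusted p under 0.05 for both doses numbered 470 higher in both, 487 lower in both and 1 in opposite directions. Independent lists of the real sizes would share 60.3 and 62.6. The simulation gave 88.4 and 63.4. With no effect its lists should hold near the nominal 5% of genes, fewer than the real 1518 and 2794, so its overlaps are not directly comparable. Between CBD3 in the digit 1 samples and CBD30 in the digit 2 samples the Pearson correlation was -0.0491, and it was -0.0884 for the converse pair (69 and 71 of 100 regroupings as high, highest others 0.333 and 0.241). The relation was not detected across the digits, where each group held 2 to 4 samples.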

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

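The tests of even division by the last digit, of an adjustment for it, of the digit as a covariate, of the treatment group as a source of spread, and of the spread without the vehicle sample coded 3.1 were chosen after the data were seen, as were the fits without 3 samples and the interaction of dose and digit. In 30 sets of 5 to 7 samples tested for a sample far from the others, 1 was found, where chance gives about 1 in 20. It was ENSRNOG00000018214 in CBD30 hearts, at 19.2 CPM in the sample coded 2.1 against 23.2 CPM in the nearest other.

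The CBD30 difference from vehicle was itself compared between the samples ending in digit 1 and digit 2. At an unadjusted p under 0.05 (edgeR interaction) it differed for 2187 of 17009 genes, where 850 is the nominal 5%. That count was not set beside random divisions. After adjustment 1 gene passed (edgeR interaction, adjusted p = 0.0323), ENSRNOG00000062478, named after its values were seen. Its log2 fold change was -2.28 in the digit 1 samples, with 3.03 CPM in vehicle and 0.631 CPM in CBD30 hearts (n = 4 and 2), and 0.95 in the digit 2 samples, with 1.77 and 3.42 CPM (n = 3 each).

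In scaled expression the samples ending in digit 1 and digit 2 hardly differed from each other. For the digit, 1 of 17009 genes had an unadjusted p under 0.05 (edgeR, 0 called). An even division by chance is argued against, since of 100 divisions only 1, the real one, had so small a median absolute difference (0.0137 log2; lowest other 0.0604). An adjustment of the counts for this digit before deposit is a candidate explanation. Values of 2 were rarer than the mean of the values 1 and 3 by a ratio of 0.56 (95% bootstrap interval 0.539 to 0.581), against 1.02 in simulated counts. Such a step may have altered group differences too, because the groups are spread unequally over the digits, and no biological explanation was tested.

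More genes than the nominal 850 had an unadjusted p under 0.05 against vehicle. For CBD30, scaling is argued against as the whole cause, since there were 2564 such genes with library size only and 2822 with relative log expression factors, and so are degrees of freedom spent on the digit (2516 with it as a covariate). Without the 3 samples farthest out on the first component the number was 1133, between the nominal number and 1.5 times it, so their part in the CBD30 excess stays open. For CBD3 the number without them was 747, below the nominal number, as those samples being the source would give. It stayed above the median of the other random divisions for CBD3 (610), so the nominal number is not a firm baseline. The 3 samples were picked for far scores on the side of their own group's mean, so a lower number was partly fixed in advance. The fit without them also has fewer samples, and leaving out single samples moved the number either way (929 to 2823 for CBD3, 1606 to 3912 for CBD30), so these were not separated.

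Vehicle samples lay farther apart than CBD3 samples on the first component, with SDs of 36.1 and 15.7. Unequal depth could not be decided (Spearman correlation of the score with the library total 0.298, 95% bootstrap interval -0.227 to 0.61, permutation p = 0.23; Pearson 0.162, permutation p = 0.52). A few abundant genes may contribute, since the score followed the share of the 10 most abundant genes (Spearman 0.62, permutation p = 0.0071, adjusted 0.014; Pearson 0.583, permutation p = 0.011, and 0.74 without the 2 samples farthest from the median share), though within the digits only for digit 1 (Spearman 0.867 against -0.0333 for digit 2, n = 9 each). The treatment group also stays open, with an SD ratio of 2.30 (one-sided permutation p = 0.0344, two-sided 0.0589, over all divisions of scores centred by group). The SD in CBD30 hearts was 31.0 (n = 5), with the sample coded 2.1 at 65.5 and the others at -15.9 to 14.9. It rests largely on that sample, so whether the spread followed the dose was not decided. A wrong label on the vehicle sample coded 3.1 stays open, since neither test decides it. Left out, its median position between vehicle (0) and CBD30 (1) was 0.897, above all other vehicle samples (highest 0.468), as a wrong label would give. That position was measured on the genes with the smallest p in the fit without this sample. Leaving it out raised the CBD30 calls from 0 to 267, so a high position there was largely fixed in advance. The CBD30 samples, each left out in the same way, lay at 0.479 to 0.948, so the measure barely separates the groups. The SD ratio was still 2.08 without the vehicle sample coded 3.1 (SD 32.6 in vehicle, one-sided permutation p = 0.0314, two-sided 0.0628, scores centred by group). The same sample bears on the CBD30 call, with 267 genes called without it and 0 with it. That is no further support for a wrong label.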

How the results depend on the processing

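The fits of 1 code digit, DESeq2 on the 17009 genes, without the 3 samples farthest out, with the first component as a covariate, all unadjusted counts under alternatives, and samples left out of the dose correlation were chosen after the data were seen. Where no cause is given, the cause was not tested. Counts at an adjusted p under 0.05 were 0 for CBD3, CBD30 and CBD30 against CBD3 in every edgeR and limma fit run, except 1 for CBD30 against CBD3 with only those groups fitted, and the left-out samples below. DESeq2 gave 19, 134 and 1 with 24347 genes tested, and 8, 160 and 1 on the 17009 genes. It differs from edgeR in size factors, in the test, and in adjusting p-values only over genes that pass its default filter on mean count. Size factors are argued against as the cause, since edgeR with relative log expression factors called 0 genes in each comparison.

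Leaving out samples gave 0 to 0 called genes for CBD3, 0 to 267 for CBD30 (267 without the vehicle sample coded 3.1, 1 without CBD30 replicate 1) and 0 to 0 between doses. Unadjusted counts ranged from 929 to 2823, 1606 to 3912 and 230 to 363, and the dose correlation from 0.682 to 0.822. Without the 3 samples farthest out the dose correlation was 0.646, and over the 8483 genes with a mean of at least 10 CPM it was 0.880. That correlation was 0.315 with the vehicles split, which removes the shared controls and also leaves fewer vehicles per dose; these were not separated.

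Unadjusted counts for CBD3 were 2249 in the digit 1 and 586 in the digit 2 samples, 747 without the 3 samples and 831 with the first component. For CBD30 they were 4265 in the digit 1 and 798 in the digit 2 samples, 1133 without the 3 and 1330 with the first component. Between doses they were 615 without a filter and 177 with at least 1 CPM in 5 samples (more and fewer genes tested), 632 with the replicate block, 449 with the first component and 839 with quality weights. All other such fits gave 1236 to 2260 for CBD3 (highest with quality weights), 2136 to 3215 for CBD30 and 234 to 421 between doses.

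The replicate numbers did not pair the samples: 2 of 8 same-number pairs correlated over 0.1 (-0.196 to 0.308), and 3 of 13 samples correlated best with their own number. With the block (14 columns) 0 genes were called in each comparison, with 1953, 2226 and 632 at an unadjusted p under 0.05. With the first number of the code as a shared unit (11 units), 0 genes were called in each comparison. The correlation within those units was -0.107, but no label says that the number marks a litter.

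Of 336 alternative values for the 4 IDs, 313 kept sign and side of the threshold, 15 passed it and 8 changed sign. All 8 were ENSRNOG00000018214 between doses, from -0.017 to 0.024 with the block, 0.094 in the digit 2 samples, 0.041 without the 3 samples, 0.058 with quality weights, and -0.068 to 0.041 with samples left out. The planned gene-list tests were not run, since no ID had a symbol. Depth differed by digit, and low genes are the least precise.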

Other observations

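Whether chance division of the samples could give as large results was tested for each comparison with 100 divisions, the real one included, and for called genes the test was chosen after the result was seen. For genes at an adjusted p under 0.05 the count of divisions decides nothing: the real number was 0, so 100 of 100 divisions give as many by construction. The highest others called 111 for CBD3, 1882 for CBD30 and 1 for CBD30 against CBD3. As many at an unadjusted p under 0.05 came from 16 divisions for CBD3 (1518, highest other 4224), 8 for CBD30 (2794, highest other 5248) and 87 between doses (294, highest other 1717), so chance was not excluded for these 3 unadjusted counts. The median of the other divisions was 610 for CBD3 and 623 for CBD30, below the real numbers, and 479 between doses, above it. Only 6, 3 and 1 of the other divisions called any gene. The division with 1882 called genes set the vehicle samples coded 3.1 and 2.2 and the CBD30 samples coded 1.1, 2.1 and 1.2 against the rest, and this 1 division may reflect a structure of the samples other than dose.

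For the dose correlation, only 1 of 100 regroupings, the real one, reached 0.761, with the highest other close at 0.758. The same held for 100 regroupings within the digits, a test chosen after the result was seen (highest other 0.750). Chance assignment of the samples is argued against by these regroupings, but the relation was not detected across the digits (-0.0491 and -0.0884, 69 and 71 of 100 regroupings as high), and the fold changes of each dose did not agree between them either (-0.134 for CBD3, -0.0495 for CBD30). Shared vehicles can also raise the correlation. With the vehicles split it averaged 0.315 (-0.11 to 0.49) and the covariance 0.0345, against 0.0649 unsplit. The split also leaves fewer vehicles per dose, which can lower the correlation, so for the correlation these were not separated. Averaged over all assignments, the covariance is not lowered by fewer vehicles, so its fall reflects the shared controls. The covariance of 0.0345 that remained was not set beside regroupings. A response common to both doses therefore stays open.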
